A study of Mus musculus with 24 samples.

How the data were processed

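Total RNA from the proximal and distal ends of the mandible and maxilla of mouse embryos at embryonic day 12.5 was hybridised to Affymetrix Mouse430_2 arrays, per the labels. The labels give 8 control arrays (2 for each of the 4 parts) and 16 knockout arrays (4 for each part), each with a replicate number. Mutant embryos were recognised by their cleft palate and skull defect, per the series notes. The deposited values are log2 expression per probe set, made by the authors with RMA, per the submitters' processing notes; no version of RMA is given in the sources used here, and whether all arrays went through a single RMA run is not stated. Array medians and ranges were read from the table and match a log2 scale. The number of arrays limits the precision.

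The table holds 45101 probe sets. The 64 control features were left out of all tests and used only to describe the arrays. Of the rest, 34945 carry 1 gene symbol, 932 several and 9160 none, and 34741 matched a gene of the RefSeq table (assembly GRCm38.p6, used only for names and for which genes neighbour each other) by gene identifier, with 0 symbols updated. For each of 18193 genes the probe set with the highest mean over the 24 arrays stood for the gene. A gene was kept when it lay above the 40th percentile of all non-control values (log2 of 6.07) on at least 2 of the 24 arrays, which left 13837 genes. The 4874 probe sets with none or several symbols that passed the same filter were tested apart, as data outside the gene comparisons, and are given only as counts.

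Comparisons were made with limma 3.58.1 in R 4.3.3 (lmFit and eBayes without trend), 2-sided, with Benjamini-Hochberg adjustment over the 13837 genes and a threshold of 0.05. For knockout against control over all parts, the 4 parts of each genotype and replicate number were averaged first, which gives 4 knockout and 2 control means and 4 residual degrees of freedom. The parts, the interactions and the comparisons of jaws and ends were contrasts of 1 fit of all 24 arrays with 8 group means. In the leave-outs that bring a group to 1 array, that array is assumed to vary like the other groups. The tests, samples, filter, gene lists, rule for naming genes and most alternatives were chosen before the data were examined. The comparisons of jaws and ends within the knockouts, the comparison of each knockout array set with control, and the alternatives with array set, a sex covariate and crossed numbers were added after the data were examined.

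The 27 gene lists were fixed before the data were examined: signalling (TGF-beta target genes, TGF-beta ligands, receptors and Smads, BMP pathway genes, WNT, Hedgehog and FGF target genes), patterning (mandibular identity, maxillary and frontonasal identity, palatal shelf genes, tooth germ genes, Hox genes) and tissues (cartilage, bone, skeletal muscle, tendon and extracellular matrix genes). The others covered cell states (cell cycle, p53 target and apoptosis, hypoxia and glycolysis, immediate early and stress genes) and markers of cell types that a dissection could hold (epithelium, endothelium, erythroid, macrophage, neuron, glia and migrating neural crest, brain and eye). Some genes stand in more than 1 list. Each list was tested with camera at its preset correlation of 0.01 on the fit of its comparison, with Benjamini-Hochberg adjustment over the 27 lists, and again with an estimated correlation and with fry. Camera compares a list with all other genes; fry asks whether its genes move, on balance, one way. Fry called 0 lists over all parts, 0, 1, 0 and 0 in the proximal mandible, distal mandible, proximal maxilla and distal maxilla, and 0 in both interactions. It called 2 between the jaws in controls, 6 in knockouts, 0 between the ends in controls, 0 in the knockout mandible, 1 in the knockout maxilla, 13 in knockouts numbered 1 and 2 and 0 in those numbered 3 and 4.

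Genes were named by a fixed rule. Over all parts these were the 12 largest rises and falls past the threshold with no overlap of the replicate means. In each part they were the 4 largest each way and in comparisons within a genotype the 10 largest each way. There too, only genes whose arrays did not overlap between the groups were taken. In the interactions they were the 5 largest each way. Where under 5 genes passed, the 5 smallest p-values were listed as not passing, and up to 4 members of each list with the smallest p were added. Tgfbr1, Xist and Y-linked genes were always listed. Predicted genes and clones were counted but not named. The text gives part of the genes so listed.

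The array sets were control arrays, knockout arrays numbered 1 and 2, and knockout arrays numbered 3 and 4. The knockouts were split by the hybridisation controls and the 3' minus 5' difference of the Gapdh and beta-actin control probe sets, never by the genes tested. The control arrays form 1 set by their genotype, so no set can hold both genotypes. Sex was read from Xist and Kdm5d. No arrays were duplicates (the highest correlation between arrays was 0.995).

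Whether the replicate numbers pair the samples was checked from the deviations from the group means across all genes tested. Within the knockouts all 24 pairs with the same number in different parts deviated together (r from 0.378 to 0.830, median 0.708). By the rule set beforehand the numbers were therefore taken to pair the knockout samples. The main fits of parts, jaws and ends still hold no replicate block, and their p-values ignore this pairing. Blocked counts are given only as alternatives. Pairs with the other number of the same array set did so almost as much (r from 0.296 to 0.773, median 0.696), so the number adds little beyond array set. In the proximal maxilla knockout numbers 1 and 2 have the opposite sex to the other parts with their number, so there a number does not mark 1 embryo, and the blocks, averages and leave-outs by number mix embryos. The 3 other parts of number 1 correlated more with proximal maxilla 2 (0.741, 0.773 and 0.761 in the distal mandible, proximal mandible and distal maxilla) than with proximal maxilla 1 (0.474, 0.671 and 0.581). Those of number 2 also correlated more with proximal maxilla 2 (0.683, 0.708 and 0.428) than with 1 (0.624, 0.698 and 0.344), so these values do not settle an exchange of the numbers. The pairing comes from these data, since no label says what a number marks. Among controls the 12 same-number pairs ranged from -0.681 to 0.584 (median -0.0528). With 2 control arrays per part, the deviations of numbers 1 and 2 mirror each other, so both numbers give the same values. Pairs with the distal mandible were negative (-0.681, -0.427 and -0.366) and the others positive (0.442, 0.584 and 0.261). Whether control numbers pair is therefore not settled. Across the genotypes the difference between numbers 1 and 2 correlated at -0.106 and -0.121 in the proximal and distal mandible. In the proximal and distal maxilla it correlated at -0.562 and -0.0992. The numbers shared by control and knockout thus do not pair.

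Each comparison was repeated with no filter, a filter at the 60th percentile (log2 of 7.70), the mean of all probe sets of a gene, without probe sets that may cross-hybridise, after another quantile normalization, after centring each array on its median, and with trend and robust options. It was also repeated with array weights, with the 3' minus 5' difference as a covariate, with a fold of at least 1.5, without sex-linked genes (those following Xist or Y-linked genes at r over 0.9), with a replicate block, with the arrays of the compared groups alone, and without each replicate number of each genotype. Shared controls were simulated with 100 draws of unchanged groups, each array set was also compared with a different control number (added after the data were examined), and other splits of the arrays were drawn 100 times or counted in full where there were 35.

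The tests were checked on simulated data with known changes in 100 genes at each size among 13837 genes. The simulated genes varied independently of each other and the simulated arrays formed no array sets. The shares and false calls below therefore need not carry over to the real arrays. Over all parts, 50% of genes changed by a log2 of 1 and 73% of those changed by 2 were called. In the 4 parts, in the order given above, 54%, 49%, 45% and 63% were called at 1 and 82%, 90%, 93% and 93% at 2. For the interactions with jaw and end these were 54% and 63%, then 80% and 88%. For the jaws in controls and knockouts they were 58% and 83%, then 96% and 99%, and for the ends of the control mandible and maxilla 59% and 45%, then 82% and 84%. Those for the ends of the knockout mandible and maxilla were 61% and 68%, then 87% and 95%, and for knockouts numbered 1 and 2 and those numbered 3 and 4 79% each, then 91% and 96%. Of the changed genes that were called 100% had the right direction, and in each comparison 3 to 11 unchanged genes were called as well (10 over all parts). In the list test the 1 moved list, cartilage genes, was called, and 1 other list was called too. Lists that share a moved gene, as palatal shelf genes share Sox5, were not set apart in this count. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.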

Results

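RNA was measured on 24 expression arrays from the mandible and maxilla of mouse embryos at embryonic day 12.5. In the knockout embryos Alk5 (gene symbol Tgfbr1), a type I receptor for TGF-beta, was deleted with Wnt1-Cre, which acts in the neural crest that forms most of the facial mesenchyme. Control littermates gave 2 arrays and knockouts 4 arrays for each of the 4 parts: the proximal and distal ends of the mandible and of the maxilla. Array medians were alike, and the number of arrays limits the precision of each value. The labels do not state which samples came from the same embryo or pool, so the p-values measure the spread between these samples.

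The knockout arrays numbered 1 and 2 stood apart from all others. The mean level of the hybridisation controls, which are added after RNA extraction, was 10.94 ± 0.34 (log2, SD, n = 8) on the control arrays, 11.95 ± 0.27 (n = 8) on knockout arrays numbered 1 and 2, and 9.49 ± 0.15 (n = 8) on those numbered 3 and 4. These array sets did not overlap. The excess of 3' over 5' signal of the Gapdh and beta-actin probe sets, which grows as RNA degrades, was 0.18 ± 0.04, 1.13 ± 0.28 and 0.08 ± 0.06 (log2, SD, n = 8 each). The median correlation between arrays, taken across all genes tested, was 0.969 between control and knockout arrays numbered 3 and 4, and 0.929 between control and those numbered 1 and 2. The array sets follow genotype and replicate number, so none can hold both genotypes. Within-set values of the genotype effect thus cannot be had, and array set and genotype cannot be told apart.

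**Figure D1:**
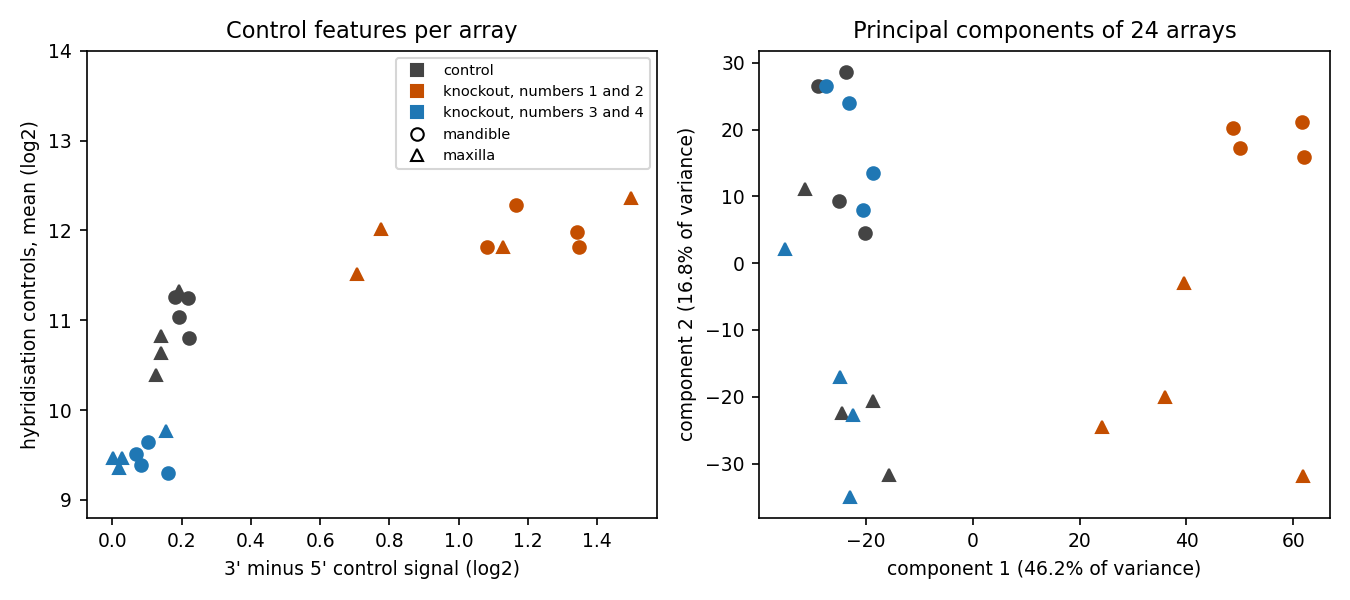
Left, mean hybridisation control level (log2) against the 3' minus 5' difference (log2) of each of the 24 arrays; right, the first 2 principal components, with 46.2% and 16.8% of the variance. Colours give the array set and symbols the jaw; the knockout arrays numbered 1 and 2 lie apart on both plots.

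Xist, expressed from the inactive X chromosome, and the Y-linked Kdm5d gave the sex of every array. Xist averaged 5.85 ± 0.20 (log2, SD, n = 16) on male and 13.39 ± 0.19 (SD, n = 8) on female arrays. All 8 control arrays were male, whereas each knockout array set held 4 male and 4 female arrays. Knockout number 3 was male and number 4 female in all parts. Number 1 was male and number 2 female, except in the proximal maxilla, where number 1 was female and number 2 male.

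Tgfbr1 itself has 3 probe sets. The brightest lay between 11.98 and 12.69 on the control arrays, between 12.07 and 12.64 on knockout arrays numbered 1 and 2, and between 12.32 and 12.52 on those numbered 3 and 4. The second averaged 7.57 ± 0.42 (SD, n = 8, range 7.02 to 8.31) in control, 5.95 ± 0.41 (5.42 to 6.62) in knockouts numbered 1 and 2 and 6.75 ± 0.22 (6.28 to 7.07) in those numbered 3 and 4. The third averaged 7.03 ± 0.28 (6.64 to 7.57), 5.10 ± 0.62 (4.33 to 5.87) and 7.63 ± 0.27 (7.24 to 7.97). Over the mean of the 4 parts the differences were 0.08 ± 0.08 (SE, adjusted p = 0.742 over all probe sets of the array), -1.22 ± 0.30 (adjusted p = 0.471) and -0.66 ± 0.93 (adjusted p = 0.801). Whether any of these probes lie in the deleted exon is not known here, so the level of Tgfbr1 checks no label.

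Knockout against control over all 4 parts asks what the loss of Alk5 in the neural crest changes in the jaws as a whole; each replicate number entered as the mean of its 4 parts. Cartilage genes were lower in the knockouts, with all 17 measured members below control and a median log2 difference of -1.10. Sox9, the transcription factor that directs cartilage formation, stood at 9.58 ± 0.06 (log2, SD, n = 4) in knockout and 10.68 ± 0.12 (SD, n = 2) in control, a difference of -1.10 ± 0.10 (SE). Acan, the large proteoglycan of cartilage, differed by -2.05 ± 0.42, and Hapln1, the link protein that holds it to hyaluronan, by -1.97 ± 0.41. The smallest p-values also belonged to Mid1, an X-linked ubiquitin ligase gene (2.01 ± 0.22), the imprinted Peg10 (-1.05 ± 0.12), the small GTPase gene Rhob (-0.78 ± 0.10) and Spry4, an inhibitor of growth factor signalling (-0.79 ± 0.11). Peg10 averaged 5.96 in knockout, below the filter level of 6.07, so its size is not well measured. No single gene passed. limma called 0 of 13837 genes, with 965 at an unadjusted p under 0.05, and the adjusted p was 0.481 for Sox9, Mid1, Peg10, Rhob and Spry4 and 0.589 for Acan and Hapln1. Adjusted over the list alone, 15 of the 17 cartilage genes were lower; the list's camera adjusted p was 3.40e-14, and its adjusted p = 0.453 with an estimated correlation. The count of 0 genes became 7279 with knockouts numbered 1 and 2 only and 216 with those numbered 3 and 4 only, and it stayed at 0 with array set as a random block. Centring each array on its median moved the median over all genes by 0.11 here, 0.13 in the distal mandible, 0.12 in the distal maxilla and 0.17 for knockouts numbered 1 and 2, so smaller differences than these have no sure direction there.

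Camera also called other lists, each with an adjusted p of 0.453 or more with an estimated correlation. All 27 extracellular matrix genes lay below control (median -0.71, camera adjusted p = 9.65e-08), among them the collagen-binding Sparc (-0.53 ± 0.10). So did all 10 tendon genes (-1.15, adjusted p = 0.00296), with Scx, the transcription factor of tendon progenitors, at -1.74 ± 0.29, and 11 of 12 bone genes (-0.72, adjusted p = 0.00184), with Smpd3 at -1.21 ± 0.28. Endothelium markers were lower in 14 of 15 members (-0.36, adjusted p = 0.00641, -0.23 without knockout 1), Tie1 by -0.47 ± 0.10. Signalling lists lay lower by less: TGF-beta target genes (-0.26, adjusted p = 0.0270), TGF-beta ligands, receptors and Smads (-0.26, adjusted p = 0.0283), FGF target genes (-0.28, adjusted p = 0.0283), palatal shelf genes (-0.41, adjusted p = 0.0332) and hypoxia and glycolysis genes (-0.17, adjusted p = 0.0270). Neuron markers (-0.54, adjusted p = 0.0283) and glia and migrating neural crest markers (-0.37, adjusted p = 0.0401) were also lower. Epithelium markers were higher in 17 of 19 members (0.37, adjusted p = 1.33e-06), with Dsp, a desmosomal protein, at 0.68 ± 0.15. Erythroid markers (0.42, adjusted p = 0.0483) and macrophage markers (0.19, adjusted p = 0.0232), with Cd68 at 0.77 ± 0.11, were higher too. The mean level of erythroid markers was 10.81, 10.67, 8.91 and 8.85 in knockouts 1 to 4. It was 9.28 and 9.35 in controls 1 and 2, so knockouts 3 and 4 lay lower. Cell cycle genes had a median of 0.04 and a mean of -0.01, against a median of -0.05 over all genes tested, and camera's direction was up (adjusted p = 0.0313). Adjusted over the list alone, 1 gene each was lower in the tendon, extracellular matrix, FGF target and endothelium lists, and 1 macrophage gene was higher.

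None of these 16 calls held with an estimated correlation: the adjusted p was 0.485 for cell cycle genes and macrophage markers, 0.540 for glia markers, 0.597 for erythroid and neuron markers, and 0.453 for the others. The RNA quality covariate ended the calls of tendon genes (camera adjusted p = 0.0976), TGF-beta target genes (0.137), TGF-beta ligands, receptors and Smads (0.137), FGF target genes (0.137), palatal shelf genes (0.0637), hypoxia and glycolysis genes (0.123), neuron markers (0.158) and glia and migrating neural crest markers (0.612). It turned erythroid markers to -0.15. Leaving out control 1 ended the calls of TGF-beta target genes (0.0723), FGF target genes (0.0597), palatal shelf genes (0.0927), cell cycle genes (0.350, median -0.04), erythroid markers (0.0551) and glia and migrating neural crest markers (0.427). It brought epithelium markers to 0.05 and turned neuron markers to 0.21. Leaving out control 2 ended those of hypoxia and glycolysis genes (0.115), erythroid markers (0.108) and macrophage markers (0.368), and moved epithelium markers to 0.59 and neuron markers to -1.56. Without knockout 3, FGF target genes (0.0557), cell cycle genes (0.161), macrophage markers (0.155), neuron markers (0.104) and glia and migrating neural crest markers (0.0557) lost theirs. Without knockout 1 or 2, erythroid markers (0.271 and 0.191) and glia and migrating neural crest markers (0.0649 and 0.0599) lost theirs, and without knockout 4 cell cycle genes did (0.0756). TGF-beta ligands, receptors and Smads kept a call in these 6 fits, with medians from -0.14 to -0.40. Cartilage, bone and extracellular matrix genes kept theirs in all of them and with the RNA quality covariate. Bone genes had no call with knockouts numbered 3 and 4 only. Array set as a random block did not enter camera's test, so no list was tested against it.

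No other list passed in this comparison with all arrays. Those lists were BMP pathway genes (-0.40, adjusted p = 0.0597), mandibular identity (-0.19, 0.0562, 2 genes lower adjusted over the list alone), maxillary and frontonasal identity (0.12, 0.0843), and WNT target genes (0.04, 0.239). The others were Hedgehog target genes (-0.04, although camera's direction was up, 0.295), tooth germ genes (median -0.07, mean 0.03, 0.756), skeletal muscle genes (-0.36, 0.371), p53 target and apoptosis genes (0.02, 0.123), immediate early and stress genes (-0.30, 0.101), brain and eye markers (-0.35, 0.295) and Hox genes (-0.08, 0.756). The direction of skeletal muscle genes turned with the control left out (0.39 without control 1, adjusted p = 4.33e-07, and -1.31 without control 2, 4.13e-10), as did that of WNT target genes (-0.27, 0.0115, and 0.34, 4.46e-06). Also past the threshold were BMP pathway genes without control 1 (0.00120), knockout 3 (0.0235) or knockout 4 (0.0248), and mandibular identity without control 1 (0.0114) or knockout 4 (0.0348). So were maxillary and frontonasal identity (0.0286) and brain and eye markers (0.0148) without control 2, and immediate early and stress genes without knockout 3 (0.0484) or knockout 4 (0.0321).

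The array sets were then compared with control one at a time; both comparisons were added after the data were examined. In knockouts numbered 1 and 2, camera called cartilage, tendon and extracellular matrix genes lower and erythroid markers higher, and no list with an estimated correlation (smallest adjusted p = 0.552). Lin28a rose by 3.10 ± 0.13 (log2, SE, n = 2 against 2 means, adjusted p = 0.00148), and Trim71 by 3.14 ± 0.11 (adjusted p = 0.00139), both RNA-binding regulators of developmental timing, and Igdcc3 rose by 4.02 ± 0.13 (adjusted p = 0.00139). Aspn fell by 6.13 ± 0.11 (adjusted p = 0.00124) and Ogn by 4.26 ± 0.11 (adjusted p = 0.00139), small proteoglycans of connective tissue, and Cnmd, chondromodulin, fell by 5.47 ± 0.33 (adjusted p = 0.00155). Aspn (3.96) and Cnmd (5.04) on these knockout arrays and Lin28a (4.57) on control arrays averaged below the filter level of 6.07, so the sizes of these 3 differences are not well measured. limma called 7279 genes, 2897 higher and 4382 lower, or 4644 higher and 3280 lower after median-centring. The 3' excess on these arrays, 1.13 against 0.18 in control, moves with every one of these groups, and with it as a covariate limma called 0 genes. With a sex covariate 2522 genes were called, and without knockout 1 4038.

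Of the cartilage genes, 15 of 17 fell in knockouts numbered 1 and 2 over all genes tested and 17 adjusted over the list alone (median -1.28); Sox9 fell by 1.05 ± 0.09 and Sox6, its partner in cartilage, by 1.58 ± 0.07. Tendon genes fell in 9 of 10 (median -2.08), with Thbs2 at -3.17 ± 0.12, and extracellular matrix genes in 24 of 27 (-1.17), with Eln, elastin, at -2.56 ± 0.11. Bone genes fell in 10 of 12 (-1.31), BMP pathway genes in 10 of 16 (-0.70), with the antagonist Nog at -1.75 ± 0.09, and palatal shelf genes in 7 of 14 (-0.75), with Osr2 at -2.45 ± 0.09. Immediate early and stress genes fell in 10 of 15 and rose in 1 (-0.66), and TGF-beta target genes fell in 10 of 17 and rose in 1 (-0.37), with the actin-binding Tagln at -1.20 ± 0.09. Endothelium markers fell in 10 of 15 and rose in 1 (-0.62), with Pecam1 at -1.24 ± 0.07, and 8 of 15 hypoxia and glycolysis genes fell (-0.29). All 8 erythroid markers rose (1.51), the embryonic globin Hbb-bh1 by 1.82 ± 0.06 and the red cell anion exchanger Slc4a1 by 2.68 ± 0.07. Epithelium markers rose in 5 of 19 and fell in 1 (0.28). Camera called these 12 lists, with adjusted p from 2.99e-07 for extracellular matrix genes to 0.0467 for TGF-beta target genes and epithelium markers, and none with an estimated correlation, where the adjusted p was 0.552 or more. With the RNA quality covariate tendon genes (-0.35, camera adjusted p = 0.449), hypoxia and glycolysis genes (0.553), epithelium markers (0.498, median -0.01), endothelium markers (0.563, median 0.41) and erythroid markers (0.15, 0.823) lost their calls. Without control 1 TGF-beta target genes (0.0632) and epithelium markers (-0.13, 0.597) lost theirs, and without control 2 hypoxia and glycolysis genes did (0.0926). The same held without knockout 1 for TGF-beta target genes (0.0533) and epithelium markers (0.101), and without knockout 2 for TGF-beta target genes (0.108), palatal shelf genes (0.0778), hypoxia and glycolysis genes (0.0590) and epithelium markers (0.0652).

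**Figure D2:**
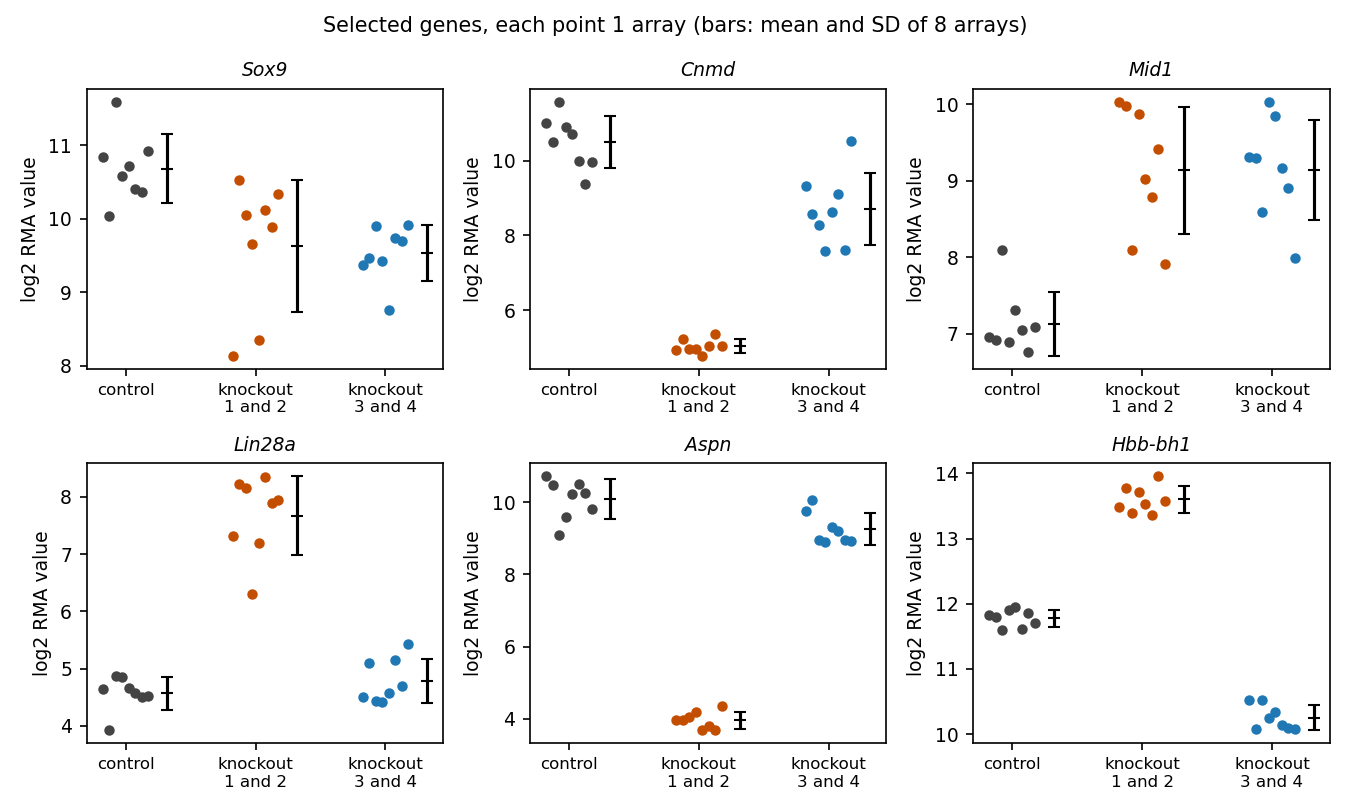
Level (log2) of Sox9, Cnmd, Mid1, Lin28a, Aspn and Hbb-bh1 on each of the 24 arrays by array set; each point is 1 array and the bars give the mean and SD of 8 arrays. Sox9 and Mid1 differ from control by a like amount in both knockout sets, whereas Lin28a, Aspn and Hbb-bh1 do not.

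In knockouts numbered 3 and 4, whose 3' excess was near that of the controls, Sox9 fell by 1.15 ± 0.08 (log2, SE, n = 2 against 2 means, adjusted p = 0.0345) and Sox6 by 0.82 ± 0.08 (adjusted p = 0.0462). Itga5, an integrin subunit that binds fibronectin, fell by 1.79 ± 0.06 (adjusted p = 0.0250), Col15a1, a basement membrane collagen, by 1.75 ± 0.06 (adjusted p = 0.0250), and Gsc, a homeobox gene of the lower jaw, by 0.64 ± 0.06 (adjusted p = 0.0486). Mid1 rose by 2.01 ± 0.14 (adjusted p = 0.0352) and Cd68, a macrophage gene, by 0.84 ± 0.07 (adjusted p = 0.0405). limma called 216 genes, 38 higher and 178 lower. Cartilage genes were lower in 17 of 17 members (median -0.97, camera adjusted p = 7.59e-06, 2 lower over all genes, 12 adjusted over the list alone), Acan by -1.59 ± 0.32 without passing (adjusted p = 0.0917). Extracellular matrix genes were lower in 22 of 27 (-0.30, adjusted p = 0.00212, 10 adjusted over the list alone, 0.266 with the RNA quality covariate). Erythroid markers were lower in 8 of 8 (-0.28, adjusted p = 0.00492, 1 lower over all genes, 3 adjusted over the list alone, 0.112 with the RNA quality covariate). Epithelium markers were higher (0.52, adjusted p = 0.000685, 0.22 without control 1), as were macrophage markers (0.15, adjusted p = 0.0196, -0.01 without control 2, and adjusted p = 0.163 without knockout 3) and cell cycle genes (0.08, adjusted p = 0.00446, 0.165 without control 1). With an estimated correlation the adjusted p was 0.704 for cartilage genes, extracellular matrix genes, epithelium and erythroid markers, 0.731 for macrophage markers and 0.825 for cell cycle genes. The gene count fell to 0 without knockout 3, without knockout 4, with a sex covariate and with the RNA quality covariate, was 65 without control 1 and 1378 without control 2, and was 83 after median-centring.

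Both array sets share the control arrays. Of the 216 genes called in knockouts numbered 3 and 4, 140 were also called in those numbered 1 and 2. These were 59 lower in both, 11 higher in both, 60 higher in numbers 1 and 2 but lower in numbers 3 and 4, and 10 the other way. Independent lists of these sizes would give 56.4, 7.96, 37.3 and 12.03. Across all genes tested, which are not independent replicates, the differences correlated at r = 0.139 with a covariance of 0.0207, and 49.7% of genes had the same sign. Simulated unchanged groups against the same controls gave r = 0.5003, a covariance of 0.0124 and 66.7% (mean of 100 draws). With control 1 for numbers 1 and 2 and control 2 for numbers 3 and 4, which share no array, r was -0.020 and 45.0% of genes had the same sign. Of 65 genes called in numbers 3 and 4, 41 were called in both, 21 lower in both where independent lists would give 15.7. With the controls the other way round r was 0.037 with 47.7%, and of 1378 genes 731 were called in both, 352 lower in both where independent lists would give 267.

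**Figure D3:**
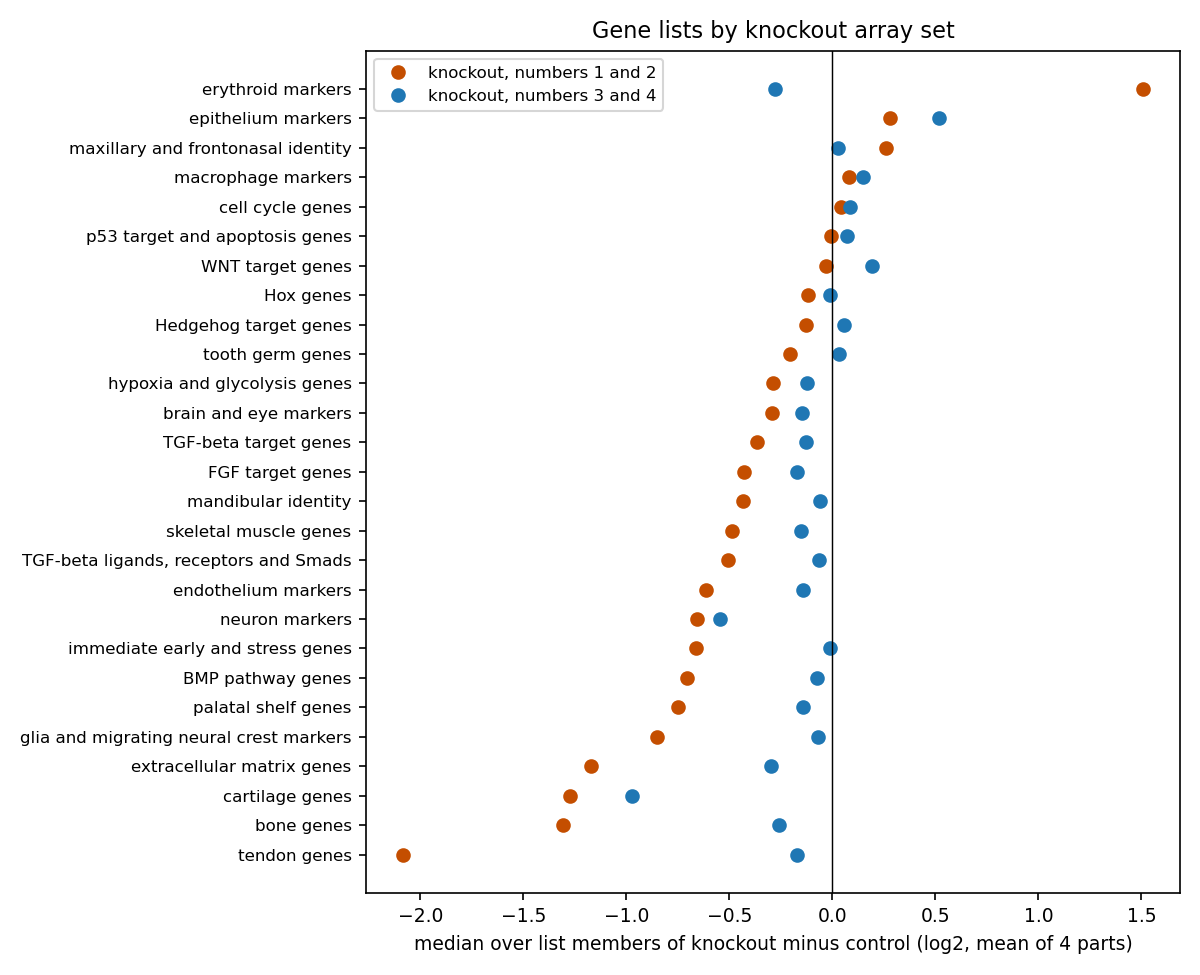
Median over list members of the knockout minus control difference (log2) for the 27 gene lists, orange for knockouts numbered 1 and 2 and blue for those numbered 3 and 4. Cartilage genes lie at -1.28 and -0.97, and erythroid markers at 1.51 and -0.28.

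Knockout was also compared with control in each part alone. In the distal mandible Rhob fell by 0.99 ± 0.14 (log2, SE, adjusted p = 0.0208), from 12.29 ± 0.16 (SD, n = 2) in control to 11.30 ± 0.15 (SD, n = 4) in knockout. In the proximal maxilla Tle1, a transcriptional corepressor, fell by 1.07 ± 0.16 (adjusted p = 0.0491), from 10.91 ± 0.19 to 9.85 ± 0.20. In the distal maxilla Adamts6, a secreted metalloprotease, fell by 1.24 ± 0.19 (adjusted p = 0.0413), from 8.62 ± 0.46 to 7.37 ± 0.16. All 4 knockout arrays lay below both control arrays for each of these genes, a condition of the rule for naming the largest differences. Rhob was lower in the other parts too, by -0.78 ± 0.14 in the proximal mandible (SE, adjusted p = 0.0902). It differed by -0.72 ± 0.14 in the proximal maxilla (0.149) and -0.63 ± 0.14 in the distal maxilla (0.333). As the mean of the 4 parts Adamts6 stood at 7.44 to 7.68 in knockouts, against 8.22 and 8.36 in controls. A call in 1 part thus does not confine a difference to it. limma called 2 genes in the distal mandible, the other an unnamed clone that was higher, 1 in each end of the maxilla and 0 in the proximal mandible (1058 at an unadjusted p under 0.05). There the smallest adjusted p, 0.0707, was that of Tns2, a focal adhesion protein, at -0.96 ± 0.16, and Tns2 also differed by -0.86 ± 0.16 in the distal maxilla (adjusted p = 0.175). With array set as a random block the adjusted p was 0.999 for Rhob and 1.00 for Tle1 and Adamts6, and with only the arrays of the part it was 0.509, 0.930 and 0.930. Rhob lost its call without control 1 (0.0816), control 2 (0.338), knockout 2 (0.119), knockout 3 (0.0978) or knockout 4 (0.179). Tle1 lost it in all 6 such fits (from 0.0804 without knockout 1 to 0.395 without knockout 3), and Adamts6 without control 1 (0.999) or knockout 1 (0.306), 2 (0.0885), 3 (0.118) or 4 (0.252). With a sex covariate Tle1 (0.0551) and Adamts6 (0.0812) lost their calls too, as they did with the mean of all probe sets (0.242 and 0.904) and median-centring (0.0544 and 0.0875). Tle1 also lost it without a filter (0.0522), and Adamts6 with another quantile normalization (0.0522) and with trend and robust options (0.0593).

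The cartilage genes lay below control in all 17 members in each part. Their median was -1.33 in the proximal mandible (camera adjusted p = 1.37e-11), -1.14 in the distal mandible (2.32e-08), -0.93 in the proximal maxilla (3.14e-08, -0.56 without control 1) and -1.13 in the distal maxilla (1.23e-13, -0.35 without control 1 and -1.94 without control 2). Adjusted over the list alone 10, 9, 0 and 12 of them were lower, and the adjusted p was 0.338, 0.621, 0.542 and 0.221 with an estimated correlation. Extracellular matrix genes had medians of -0.73 (adjusted p = 2.08e-06), -0.84 (3.26e-07), -0.51 (0.000171, 0.119 with the RNA quality covariate) and -0.68 (2.81e-09), with adjusted p = 0.482, 0.621, 0.596 and 0.333 with an estimated correlation. Endothelium markers were lower in 15 of 15 members in the proximal mandible (-0.44, adjusted p = 9.23e-05, adjusted p = 0.338 with an estimated correlation) and in the distal maxilla (-0.42, adjusted p = 0.000107, adjusted p = 0.311 with an estimated correlation). FGF target genes lay lower in the distal mandible (-0.32, adjusted p = 0.0137, 0.0647 with the RNA quality covariate, adjusted p = 0.621 with an estimated correlation), with 2 of 11 lower adjusted over the list alone. Palatal shelf genes lay lower in the distal maxilla (-0.62, adjusted p = 0.00860, 0.0677 without knockout 2 and 0.0935 with the RNA quality covariate, adjusted p = 0.311 with an estimated correlation). Camera called 11, 9, 9 and 14 of the 27 lists in the 4 parts, and none with an estimated correlation. With knockouts numbered 3 and 4 only, 217, 281, 293 and 226 genes were called, and with those numbered 1 and 2 only, 4319, 5938, 2754 and 3475.

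Whether the genotype effect differs between the jaws was tested by the interaction. The spread of this fit includes the gap between the knockout array sets, so few calls do not show like effects in both jaws. Macrophage markers were lower in mandible relative to maxilla in 15 of 15 members (median -0.48, camera adjusted p = 3.57e-11, adjusted p = 0.382 with an estimated correlation), the chemokine receptor gene Cx3cr1 by -0.63 ± 0.30 (log2, SE, adjusted p = 1). WNT target genes were lower in 14 of 15 (-0.62, adjusted p = 1.14e-06, adjusted p = 0.594 with an estimated correlation), with the WNT inhibitor Wif1 at -2.12 ± 0.97 (adjusted p = 1). limma called 0 genes, with 107 at an unadjusted p under 0.05; the smallest p-values were those of Adamts8, Ror2, Tac2, Lrrc75b and Ccnb3, all with adjusted p = 1. Without control 1 the median of WNT target genes was -0.04 (0.856) and without control 2 -1.18, and limma called 1 gene without control 2.

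The interaction of genotype with the ends (distal minus proximal) gave 32 of 33 cell cycle genes below 0 (median -0.14, camera adjusted p = 3.73e-05), with the cyclin gene Ccnd1 at -0.55 ± 0.20 (log2, SE, adjusted p = 1). Neuron markers lay above 0 in 13 of 14 (0.88, adjusted p = 0.000282), with Isl1, a homeobox gene of sensory and motor neurons, at 1.65 ± 0.59 (adjusted p = 1). Each had an adjusted p = 0.546 with an estimated correlation. The gap between the knockout array sets enters the spread here too, so few calls do not show like effects at both ends. limma called 0 genes, with 157 at an unadjusted p under 0.05; the smallest p-values were those of Gpr25, Kcnmb2, Htr3a, Dlx1 and Masp1, all with adjusted p = 1. Cell cycle genes lost the call without control 1 (-0.03, 0.251) or knockout 1 (-0.02, 0.197) and neuron markers without control 1 (0.23, 0.963); limma called 2 genes without control 1, 1 without control 2 and 3 with knockouts numbered 1 and 2 only.

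Mandible against maxilla in the controls shows the normal difference between the jaws. Hand2, a transcription factor that specifies the lower jaw, was higher in the mandible, 12.01 ± 1.06 (log2, SD, n = 4) against 7.93 ± 0.90 (SD, n = 4), a difference of 4.08 ± 0.65 (SE, adjusted p = 0.00922). Pitx1, a homeobox gene of the mandible and hindlimb, was higher by 2.16 ± 0.30 (adjusted p = 0.00529). Higher in the maxilla were Neurod1, a neuronal differentiation factor, by -4.27 ± 0.70 (mandible minus maxilla, adjusted p = 0.0114), and Gata2 by -2.92 ± 0.42 (adjusted p = 0.00529). So were Sox2, a factor of neural and epithelial progenitors, by -1.96 ± 0.29 (adjusted p = 0.00678), and Lrrc75b by -2.10 ± 0.22 (adjusted p = 0.000278). None of these genes overlapped between the 4 mandible and 4 maxilla arrays, a condition of the rule for naming the largest differences. limma called 25 genes, 7 higher in mandible and 18 higher in maxilla. The mandibular identity list was higher (median 0.97, camera adjusted p = 1.39e-15, adjusted p = 0.000230 with an estimated correlation), with 2 of 12 genes higher over all genes and 8 adjusted over the list alone. Brain and eye markers were lower (-2.08, adjusted p = 4.87e-09, adjusted p = 0.00774 with an estimated correlation), with 1 of 8 lower over all genes and 5 adjusted over the list alone. Skeletal muscle genes were higher in the mandible in 30 of 31 (1.94, adjusted p = 3.30e-25, adjusted p = 0.118 with an estimated correlation, 2.99 without control 1 and 0.66 without control 2). Hox genes were higher there in 9 of 10 (0.63, adjusted p = 4.07e-07, adjusted p = 0.0858 with an estimated correlation). Hand2 lost its call without control 2 (0.199), knockout 1 (0.0536) or knockout 4 (0.0544), Pitx1 without control 2 (0.0511), Neurod1 without knockout 1 (0.0633) or 3 (0.0690) and Gata2 without control 2 (0.0611), while Lrrc75b and Sox2 kept theirs in all 6 such fits. The gene count was 0 with the 8 control arrays alone, 131 with array weights, 93 with the RNA quality covariate, 16 with a sex covariate, and 11, 13, 13 and 9 without knockout 1, 2, 3 and 4.

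The same comparison in the knockouts, added after the data were examined, gave Hand2 higher in the mandible by 4.33 ± 0.46 (log2, SE, adjusted p = 7.19e-05), 11.89 ± 1.01 (SD, n = 8) against 7.56 ± 1.14 (SD, n = 8). Dlx6 and Dlx5, homeobox genes that pattern the lower jaw, were higher by 2.01 ± 0.23 (adjusted p = 8.41e-05) and 1.28 ± 0.22 (adjusted p = 0.00399), and Pitx1 by 2.09 ± 0.21 (adjusted p = 7.19e-05). Higher in the maxilla were Neurod1 by -4.04 ± 0.49 (mandible minus maxilla, adjusted p = 0.000223), Sp8, a factor of the facial ectoderm and brain, by -3.35 ± 0.50 (adjusted p = 0.00113), and the forebrain and eye gene Six3 by -2.0 ± 0.28 (adjusted p = 0.000631). Of these, Dlx5 alone overlapped between the jaws. limma called 326 genes, 158 higher in mandible and 168 higher in maxilla. The mandibular identity list was higher (median 1.31, camera adjusted p = 2.84e-21, adjusted p = 3.25e-05 with an estimated correlation, 8 of 12 over all genes and 10 adjusted over the list alone). Skeletal muscle genes were higher too (2.31, adjusted p = 1.25e-38, adjusted p = 0.0417 with an estimated correlation, 16 of 31 over all genes, and 28 higher and 1 lower adjusted over the list alone). Brain and eye markers were lower (-1.93, adjusted p = 2.48e-09, adjusted p = 0.00709 with an estimated correlation, 5 of 8 over all genes and over the list alone). Neuron markers were lower too (-1.85, adjusted p = 2.61e-11, adjusted p = 0.138 with an estimated correlation, 4 of 14 over all genes, 9 adjusted over the list alone). With replicate number as a block the gene count was 868; it was 59, 71, 97 and 171 without knockout 1, 2, 3 and 4, 49 with numbers 3 and 4 only, 827 with the RNA quality covariate and 2235 with array weights. With numbers 3 and 4 only Pitx1 (0.0665), Neurod1 (0.123), Sp8 (0.216) and Six3 (0.136) lost their calls, and with numbers 1 and 2 only Sp8 did (0.0722).

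Of the 25 genes called between the jaws in controls, 22 were called in the same direction in knockouts, where independent lists of these sizes would share 0.299. These comparisons share no array, although they share 1 estimate of the spread. Across the 326 genes called in knockouts, which are not independent replicates and were chosen for their difference there, 321 had the same sign in controls.

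**Figure D4:**
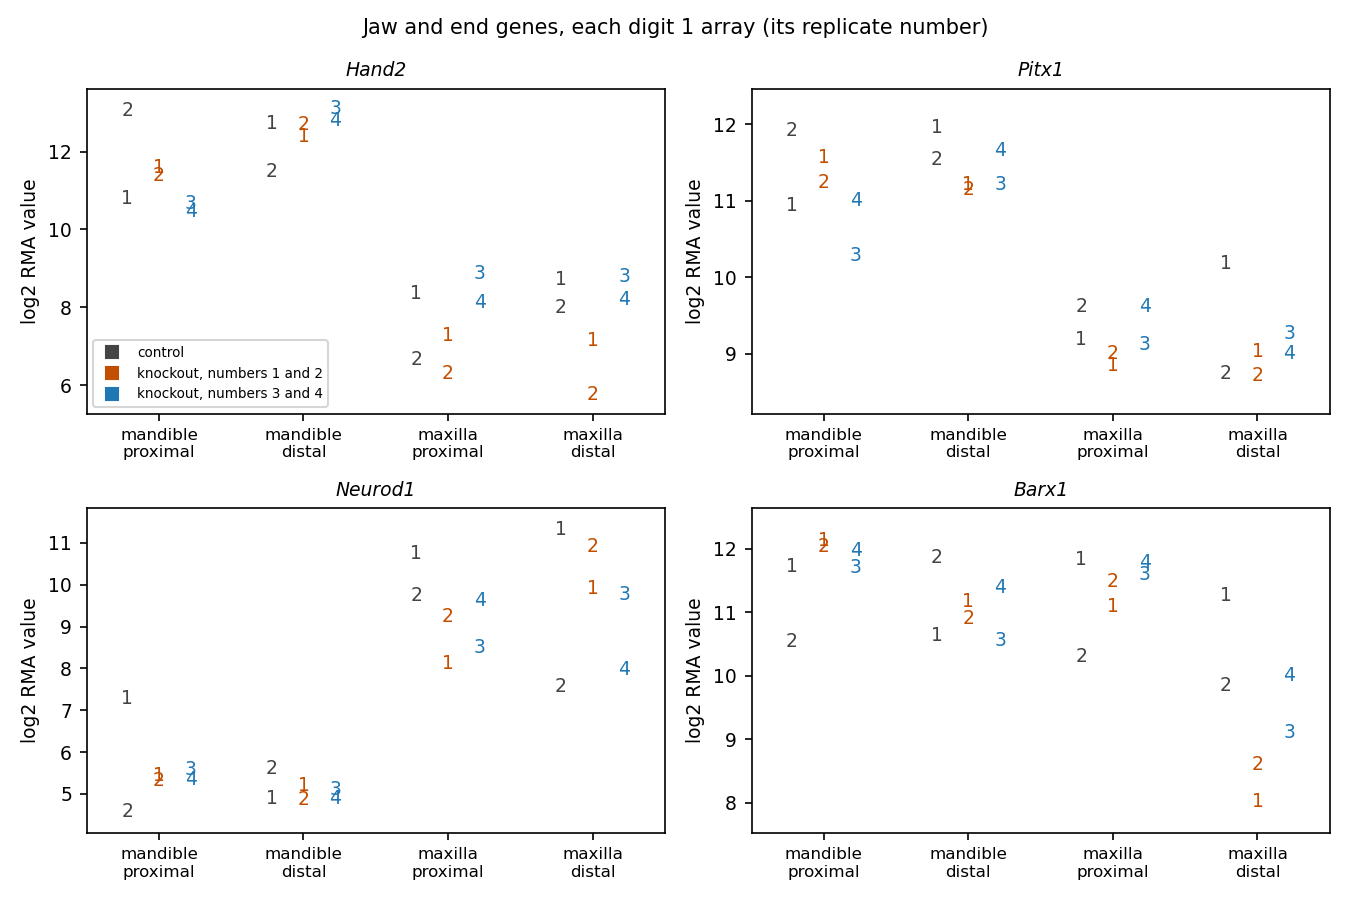
Level (log2) of Hand2, Pitx1, Neurod1 and Barx1 in each part in controls and knockouts; each digit is the replicate number of 1 array. Hand2 averages 12.01 in control mandible and 7.93 in control maxilla, and 11.89 and 7.56 in the knockouts.

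Distal against proximal in the control mandible and maxilla asks how the ends of each jaw differ. In the maxilla neuron markers were lower distally in 14 of 14 members (median -1.34, camera adjusted p = 5.44e-09, adjusted p = 0.654 with an estimated correlation, -0.47 without control 1). Skeletal muscle genes were lower distally in 31 of 31 (-0.84, adjusted p = 1.36e-10, adjusted p = 0.720 with an estimated correlation, 0.02 without control 1 and -1.85 without control 2). In the mandible cartilage genes were lower distally in 16 of 17 (-0.26, adjusted p = 0.000746, adjusted p = 0.994 with an estimated correlation, 0.594 without control 2). limma called 0 genes in the mandible, with 8 at an unadjusted p under 0.05, and 0 in the maxilla, with 191. With no difference a share of about 0.05 of the 13837 genes would lie there. The spread of this fit includes the gap between the knockout array sets, so these counts do not show that the ends are alike. The smallest p-values were those of Tcam1, Hpca, Oc90, Kpna7 and Serp2 in the mandible and of Zdhhc22, Akain1, Otud7a, Klhl14 and Kdf1 in the maxilla, all with adjusted p = 1. Without control 2 limma called 3 genes in the mandible and 60 in the maxilla, and without control 1 1 gene in the mandible.

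In the knockout mandible, a comparison added after the data were examined, the distal end had more Masp1, a protease of the complement system, by 1.86 ± 0.24 (log2, SE, adjusted p = 0.00394), at 8.71 ± 0.53 (SD, n = 4) against 6.85 ± 0.34 (SD, n = 4). Tbx5, a T-box transcription factor, was higher distally by 0.98 ± 0.15 (adjusted p = 0.0146), and Flt4, a receptor of lymphatic and other endothelium, by 0.55 ± 0.10 (adjusted p = 0.0294). Gbx2, a homeobox gene, was lower distally by -3.29 ± 0.55 (adjusted p = 0.0227), Slitrk4, a neuronal membrane protein, by -2.66 ± 0.40 (adjusted p = 0.0122), and Adarb2 (-1.49), Dach2 (-1.33) and Gpr25 (-1.12) were lower too, all 8 genes without overlap between the ends. limma called 8 genes, and 41 with replicate number as a block. Macrophage markers were lower distally in 15 of 15 members (median -0.62, camera adjusted p = 1.87e-14, adjusted p = 0.141 with an estimated correlation), 7 of them adjusted over the list alone. Endothelium markers were higher in 14 of 15 (0.17, adjusted p = 0.000182, adjusted p = 0.422 with an estimated correlation). Maxillary and frontonasal identity was lower (-0.88, adjusted p = 0.0175, adjusted p = 0.141 with an estimated correlation, 0.0750 with the block), with 2 of 13 genes higher and 5 lower adjusted over the list alone. The gene count was 0 without knockout 1, 2 or 3, 3 without knockout 4, 21 without either control, and 18 with the 8 arrays alone, where of the 8 named genes Adarb2 alone kept its call (0.0294) and the others had an adjusted p from 0.0713 (Tbx5) to 0.0826 (Flt4). It was 46 with numbers 1 and 2 only, where Tbx5 (0.104), Flt4 (0.124) and Adarb2 (0.128) lost theirs, and 2 with numbers 3 and 4 only, where all 8 did (from 0.224 for Flt4 to 0.814 for Gbx2). Tbx5 (0.149) and Slitrk4 (0.0816) lost theirs with the mean of all probe sets, and Flt4 did with trend and robust options (0.0550) and a sex covariate (0.0527). The count was 54 with the RNA quality covariate and 303 with array weights.

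In the knockout maxilla, also added after the data were examined, Gria1, a glutamate receptor subunit, was lower distally by -2.08 ± 0.28 (log2, SE, adjusted p = 0.0108), at 5.48 ± 0.35 (SD, n = 4) against 7.55 ± 0.41 (SD, n = 4). It was the 1 gene limma called. Barx1 (-2.55 ± 0.43, adjusted p = 0.0572) and Dlx1 (-2.76 ± 0.47, adjusted p = 0.0572), homeobox genes of the proximal arches, and Lhx6 (-3.10 ± 0.59, adjusted p = 0.115) had larger differences that did not pass. Palatal shelf genes were lower distally in 12 of 14 members (median -0.43, camera adjusted p = 0.000113, adjusted p = 0.0584 with an estimated correlation). The p53 target and apoptosis genes were higher in 13 of 14 (0.09, adjusted p = 0.00159, adjusted p = 0.0337 with an estimated correlation, 0.17 without knockout 2). Skeletal muscle genes were lower in 30 of 31 (-1.05, adjusted p = 6.97e-10, adjusted p = 0.355 with an estimated correlation, -0.43 without knockout 4). Epithelium markers were higher in 17 of 19 (0.49, adjusted p = 1.10e-06, adjusted p = 0.221 with an estimated correlation, 0.30 without knockout 4). With replicate number as a block 5 genes were called. Gria1 lost its call without knockout 2 (0.556), 3 (0.132) or 4 (0.103), within the 8 arrays alone (0.333) and within either array set (0.358 and 0.330), while 10 genes were called without either control and 4728 with array weights.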

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

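All tests of explanations in this part were chosen after the result was seen, except the slope on RNA quality.

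The knockout arrays numbered 1 and 2 stand apart from those numbered 3 and 4. Over the 8 arrays numbered 1 and 2, the slope of the array set score on the 3' excess accounts for 48.9% of the gap between the sets (95% interval 28.6 to 69.3). Whether loss of RNA quality is the cause cannot be told, since the interval spans the 50% bound set beforehand and ends short of 100%. The interval also takes the 8 arrays as independent, although they carry only numbers 1 and 2. The score was built from these same arrays, so the bounds are not sure. The hybridisation controls, which hold no embryonic RNA, differ by 2.46 (log2). The knockouts were split by these controls, so the difference cannot test a separate run of hybridisation, which stays open. An earlier stage of the embryos is a candidate explanation for part of it: 5 genes known to decline in mid-gestation (Hmga2, Igf2bp1, Igf2bp3, Nr6a1 and Arid3a, the tested ones of 7 listed) were all higher than in control, with a median of 0.67 (p = 0.0900 with an estimated correlation), and none of the 3 explanations excludes the others.

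The ends of 1 control mandible may be out of place. On 8 genes that separate the ends of the knockout mandibles (distal minus proximal score from 1.14 to 2.03, SD 0.43), control 1 scored 0.47 and control 2 -0.74. Both lie below all knockout numbers. These genes were called in the same knockout arrays, so the knockout scores are raised by that choice and make a poor yardstick. The distal array of each number resembles the proximal array of the other (r = 0.993 and 0.995 across genes) more than the other distal array (0.984). The proximal arrays correlated with each other at 0.973, and the ends with the same number at 0.980 in both numbers. Exchanged labels of the ends of 1 control mandible would give this, but these correlations do not tell in which number. A shifted line of dissection stays open as well, since the score of control 2 is -1.74 SD of the knockout numbers from 0, inside the bound of 2 SD. No label was changed, and the ends of the control mandible, knockout against control in each end of the mandible and the interaction with the ends all rest on these arrays.

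Cartilage genes were lower than in control in both knockout array sets in camera's test, but not past the threshold with an estimated correlation (adjusted p = 0.669 and 0.704). Sex does not account for it, because in the male knockout number 3 their median was -1.11 against the male controls (-1.33, -1.22 and -0.88 in numbers 1, 2 and 4; controls 1 and 2 lie at 0.36 and -0.36 around their mean). An earlier stage is argued against for numbers 3 and 4, where the stage genes had a median of -0.059. Array set cannot be told apart from genotype. The sets follow genotype and replicate number, so the count of sets with both genotypes is 0 by definition and tests nothing. Genotype, the biological explanation that the design names, therefore stays open beside a difference between runs.

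Other splits of the arrays were run for the gene counts, and each count of splits holds the real one. For the interaction with jaw, where limma called 0 genes (107 at unadjusted p under 0.05), all 100 splits gave at least as many (highest other 256). For that with the ends, also with 0 genes (157 at unadjusted p under 0.05), all 100 did (highest other 3). Every split must reach a count of 0, so these splits say nothing about chance. For the jaws in controls, 12 of 100 splits gave at least the real 25 (highest other 92), so the splits do not exclude chance. However, 22 of these 25 genes were called in the same direction in the knockouts, which share no array with the controls, where independent lists would give 0.299, and this argues against chance for them. For the jaws in knockouts, 3 of 100 gave at least the real 326, but these splits mix the array sets and so cannot exclude chance. The highest other, 6257, points to a structure of the samples. Among 100 splits drawn within replicate numbers the real one was highest (next 273), which argues against chance. For the ends of the knockout mandible, 2 of 35 splits gave at least the real 8, and for those of the knockout maxilla 2 of 35 gave at least the real 1, so chance is not excluded. The highest other splits, with 7362 and 4706 genes, set numbers 1 and 2 against numbers 3 and 4 and thus follow array set. The blocked counts are 41 and 5, and among the 8 splits that part every number the highest other was 0 in both jaws, too few splits for a share under 0.05.

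A value apart from the others of its group, relative to their spread, was found in 6 of 133 groups, where chance gives 5%; 1 of them is a mean of 4 arrays. Rhob, as the mean of 4 arrays, stood at 11.32 in knockout number 1 and 11.48 to 11.50 in the others. Adgrb2 stood at 8.76 in knockout distal mandible replicate 3, against 8.69 to 8.70, a gap that is small in size. Tbx5 stood at 6.95 in control proximal mandible replicate 1, against 7.37 to 7.38 in the other control mandibles. Foxl2os stood at 9.62 in control proximal maxilla replicate 1, against 7.65 to 7.82 in the other control maxillae. Tcf21 stood at 5.68 in knockout proximal maxilla replicate 4, against 3.96 to 4.47 in the other knockout maxillae. Nhlh2 stood at 7.02 in knockout distal mandible replicate 3, against 4.14 to 5.16 in the other knockout mandibles.

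The genotype effect differed between groups for 9 lists in camera's test of the interaction, and for 0 with an estimated correlation. Between mandible and maxilla the medians of genotype effect were -0.25 for BMP pathway genes (camera adjusted p = 0.0440), -0.62 for WNT target genes (1.14e-06), 0.28 for skeletal muscle genes (0.00955) and -0.48 for macrophage markers (3.57e-11). With an estimated correlation the adjusted p was 0.967, 0.594, 0.967 and 0.382. Of these, macrophage markers alone kept the call without each control or knockout number. BMP pathway genes lost it without control 1 (-0.083) or knockout 1 (-0.11), and WNT target genes without control 1 (-0.043). Skeletal muscle genes lost it without knockout 1 (0.22) and, with the sign turned, without knockout 3 (-0.063), and turned to -0.55 without control 1 (0.000416). Between distal and proximal ends they were 0.23 for BMP pathway genes (0.0205), -0.14 for cell cycle genes (3.73e-05), -0.38 for macrophage markers (6.87e-06), 0.88 for neuron markers (0.000282) and -0.37 for glia and migrating neural crest markers (0.0124). With an estimated correlation the adjusted p was 0.771 for BMP pathway genes and 0.546 for the others. No list kept the call without each number. BMP pathway genes lost it without control 2 (0.058), knockout 2 (0.14) or knockout 4 (0.24), cell cycle genes without control 1 (-0.029) or knockout 1 (-0.017), and neuron markers without control 1 (0.23). Macrophage markers lost it without control 2 (0.046), and glia and migrating neural crest markers without control 2 (0.32) or knockout 4 (-0.35).

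Among the 4874 tested probe sets with none or several gene symbols, which no comparison of genes uses, limma called 1 between knockout and control in the proximal maxilla, 14 between the jaws in knockouts, 3488 between knockouts numbered 1 and 2 and control, 1 between those numbered 3 and 4 and control, and 0 in each other comparison.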

How the results depend on the processing

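The alternatives named for each comparison in advance were planned; those with array sets, a sex covariate and crossed numbers, and all for the comparisons within knockouts and of single array sets, were chosen after the data were seen. The values are counts of genes called, and except where stated the cause of a change was not tested. No count of a comparison changed by over 1.5 times when probe sets that may cross-hybridise or sex-linked genes were left out. Cartilage genes kept a negative median and a camera call in all parts, over all parts and in both array sets. This held under each leave-out, scaling, covariate and replicate block run. Random blocks did not enter camera's test, so no list was tested against them. With an estimated correlation 0 lists held, except 2 between the jaws in controls, 3 in knockouts and 1 between the ends of the knockout maxilla.

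Over all parts the count of 0 became 679 with the RNA quality covariate, 1453 with the 24 samples taken as independent, 1 with genotype and number as a random block, 7279 with knockout numbers 1 and 2 only and 216 with numbers 3 and 4 only. Apart from the replicate block by number it stayed at 0 in the other 18 alternatives, leave-outs included (0 to 0). With the RNA quality covariate the counts were 290, 354, 228 and 108 in the proximal mandible, distal mandible, proximal maxilla and distal maxilla (0, 2, 1 and 1 before). They were 93 between the jaws in controls (25 before), 827 in knockouts (326 before), 54 and 6 between the ends of the knockout mandible and maxilla (8 and 1 before), and 0 for knockouts numbered 1 and 2 (7279 before) and for those numbered 3 and 4 (216 before). For Hbb-bh1 in numbers 1 and 2 the covariate left the difference (1.82 to 1.90) and raised its SE from 0.06 to 0.64. Of the genes picked by the naming rule for numbers 1 and 2, it turned the sign of 29 and ended the calls of the other 86. Among the 29 were Agtr2, at 1.83 ± 6.01 (from -3.90), and Hoxd1, at 1.23 ± 3.42 (from -3.29). A sex covariate gave 1 in the proximal mandible, 16 between the jaws in controls, 2522 for numbers 1 and 2 and 0 for numbers 3 and 4; either covariate leaves 1 of 2 residual degrees of freedom in these last 2 comparisons.

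In the parts, array weights gave 334, 1260, 155 and 57 genes, knockout numbers 1 and 2 only gave 4319, 5938, 2754 and 3475, and numbers 3 and 4 only 217, 281, 293 and 226. Without a filter the proximal mandible had 1 and the proximal maxilla 0, and with the stricter filter the distal mandible had 6 and the proximal maxilla 2. The mean of all probe sets gave 11, 7, 0 and 0 in the 4 parts. Another quantile normalization gave 6 in the proximal mandible, 3 in the proximal maxilla and 0 in the distal maxilla; median-centring gave 0 in both ends of the maxilla, and trend and robust options 0 in the distal maxilla. The arrays of the part alone, which leave fewer residual degrees of freedom, gave 0 in the distal mandible and both ends of the maxilla, as did array set as a random block. Leaving out 1 replicate number, which also removes samples, gave 0 to 5 in the proximal mandible, 0 to 3 in the distal mandible, 0 to 37 in the proximal maxilla and 0 to 27 in the distal maxilla.

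The interaction with jaw gave 0 to 1 in the leave-outs, and that with the ends 0 to 2, and 3 with knockout numbers 1 and 2 only. Between the jaws in controls, array weights gave 131, the 8 control arrays alone 0 and the leave-outs 9 to 32; in knockouts array weights gave 2235, numbers 3 and 4 only 49 and the leave-outs 59 to 435. Between the ends of the control mandible and maxilla the leave-outs gave 0 to 3 and 0 to 60. In the knockout mandible array weights gave 303, the 8 arrays alone 18, numbers 1 and 2 only 46, numbers 3 and 4 only 2 and the leave-outs 0 to 21. In the knockout maxilla the stricter filter gave 3, the mean of all probe sets, another quantile normalization and median-centring 4 each, array weights 4728, the 8 arrays alone 0, numbers 1 and 2 only 0 and the leave-outs 0 to 10. For knockouts numbered 1 and 2 a fold of at least 1.5 gave 3492 and the leave-outs 4038 to 6579. For those numbered 3 and 4 the stricter filter gave 363, median-centring 83, trend and robust options 901 and the leave-outs 0 to 1378. Of the 326 genes called between the jaws in knockouts 319 were also called with array weights, and of the 7279 in numbers 1 and 2, 6177 after median-centring.

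A replicate block by number gave 6393 over all parts and 5981, 6709, 4987 and 5723 in the 4 parts. Knockout numbers 3 and 4 have no control with their number, so by its construction this fit compares numbers 1 and 2 with control; the numbers do not pair the genotypes, and for knockouts numbered 3 and 4 it could not be fitted. A replicate block of genotype and number gave 63 between the jaws in controls, where pairing by number is not settled, and 868, 41 and 5 in the knockout comparisons. There the same-number pairs hardly exceed pairs within an array set (median r of 0.708 and 0.696) and the proximal maxilla departs in sex for numbers 1 and 2, so these counts may reflect array set and not pairs of embryos. The block changed no other count by over 1.5 times. In the control mandible the same-number ends deviated in opposite directions (r = -0.681), and with the numbers crossed the replicate block called 0 genes. Arrays report signal over background, so genes near or below the filter level of 6.07 are measured least well. Genes named in the text that averaged below it in at least 1 group of a comparison include Adarb2, Agtr2, Aspn, Ccnb3, Cnmd, Foxl2os, Gbx2, Gpr25, Gria1, Hba-a2, Hemgn, Hoxd1, Klhl14, Kpna7, Lin28a, Lrrc75b, Neurod1, Nhlh2, Nog, Panx3, Peg10, Six3, Slitrk4, Sp8, Tac2, Tcam1 and Tcf21.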

Other observations

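The comparisons in this part, each of a single array set with control, were all chosen after the data were seen. The globin and histocompatibility genes named here were picked after their values were seen, for their opposite signs in the array sets. Hbb-bh1, an embryonic globin, was 1.82 ± 0.06 (log2, SE) higher than in control in knockouts numbered 1 and 2 and -1.53 ± 0.08 in those numbered 3 and 4 (limma adjusted p = 0.00139 and 0.0252). Hba-a2, an adult globin, was -0.69 ± 0.17 and 1.45 ± 0.09 (0.0277 and 0.0345). Its means in controls (5.75 and 5.97) and in knockouts 1 and 2 (4.953 and 5.398) lie below the filter level of 6.07. The control means enter both differences, so neither is well measured. The histocompatibility genes H2-K1, at -0.49 ± 0.10 and 1.20 ± 0.06 (0.0165 and 0.0258), and H2-D1, at -0.96 ± 0.10 and 1.29 ± 0.08 (0.00280 and 0.0345), had the same signs as Hba-a2. In knockouts numbered 3 and 4 limma called 0 genes without knockout 3 or without knockout 4, so these calls rest on both. Without knockout 3 Hbb-bh1 was -1.62 ± 0.07 (adjusted p = 0.324) and Hba-a2 1.43 ± 0.13 (0.375).

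Among the tested genes next to Tgfbr1 on its chromosome, 10 on each side, Col15a1 and Alg2 stand nearest and were lower in both array sets. Of these 20 neighbours 12 passed in numbers 1 and 2 (60% against 52.6% of all genes tested) and 3 in numbers 3 and 4 (15% against 1.56%). Col15a1 differed by -0.97 ± 0.08 in numbers 1 and 2 (limma adjusted p = 0.00185) and -1.75 ± 0.06 in numbers 3 and 4 (0.0250), and Alg2, a glycosyltransferase gene, by -0.48 ± 0.07 (0.00574) and -0.58 ± 0.06 (0.0486). In numbers 1 and 2 Erp44 (-1.14) and Tmeff1 (-1.18) fell by more than Col15a1. Hemgn, a gene of blood-forming cells, was the third to pass in numbers 3 and 4, at 1.20 ± 0.09 (0.00177) and -0.70 ± 0.06 (0.0405), with means of 5.12 in control and 4.42 in numbers 3 and 4 that lie below the filter level of 6.07.

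Elsewhere in the genome, and also picked after their values were seen, Panx3, a channel of cartilage and bone, was -2.84 ± 0.08 (0.00139) and -1.71 ± 0.08 (0.0250). Its means in knockouts 1 to 4 (4.49, 4.60, 5.60 and 5.76) lie below the filter level of 6.07, so these sizes are not well measured. Also lower were Peg10, whose knockout mean of 5.96 lies below that level too, at -1.04 ± 0.12 (0.00325) and -1.07 ± 0.08 (0.0387), and Rhob, at -0.83 ± 0.08 (0.00259) and -0.73 ± 0.05 (0.0352).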
